A study of Mus musculus with 6 samples.

How the data were processed

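Single-cell RNA libraries of cultured mouse retinal Müller glia were analysed, 6 in all and 1 per treatment: control RNAs, let-7 antagomiR (an inhibitor of the let-7 miRNAs), miR-25 mimic, miR-124 mimic, let-7 antagomiR with miR-25 mimic (the double combination), and those 2 with miR-124 mimic (the triple combination). Each RNA was transfected at 500 nM with Lipofectamine, per the labels' protocols. Libraries were made with the 10x Genomics V2 system, per the labels' protocols. The authors deposited raw UMI counts per gene and cell; Cell Ranger 2 and Seurat 2 with the mm10 genome are named in the submitters' processing notes, and the cell filters the authors applied are not given in the sources used here. The miRNA arms of the mimics are not stated in the labels, and the 3p arms of miR-25 and miR-124 were assumed.

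The count matrix of the double combination holds only part of its library. Its size line gives 8637523 entries and 5094879 complete ones were read, so 3014 of 5141 barcodes were used, in the order of the barcode list. The other 5 matrices were complete. No table column belonged to an unassigned sample.

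Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, and cells called doublets by Scrublet (run per library in scanpy 1.11.5 with default settings) were removed. Scrublet marked 0.103% of cells in the control library, 0.171% in the miR-25 library, 0.153% in the library labelled miR-124 and 0.142% in the library labelled triple combination, so it did not work there. It marked 2.10% in the let-7 antagomiR library and 1.16% in the double combination. Doublets are therefore weighed by 2 alternatives: leaving out the 4% of cells with the highest scores per library, and leaving out an unnamed cluster of 698 cells that carried markers of several classes.

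All kept cells were clustered together on log-normalised counts (2000 variable genes, 30 principal components, Leiden resolution 0.6) with no integration, because library and treatment are the same thing here. Clusters were named "-like" with marker genes fixed before the data were examined, but the number of markers behind a name varied. Müller-like cells fell into 3 clusters. Of the Müller glia list, 16 genes in the cluster led by Car14 were at least 2-fold over the median cluster. The cluster led by Lcn2 had 15 and that led by Grem1 had 8, where the unnamed cluster had 7. The Car14-led cluster held 691 of the Müller-like cells of the library labelled miR-124 and 1727 of those labelled triple combination, against 16 or fewer in each of the others, so the class does not hold the same cells in every library. Its defining genes are not reported as results of clustering.

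Counts were summed per library over Müller-like cells, 3594109 to 11684760 UMIs per library, and expressed as CPM (UMI counts of a gene scaled to a common library total). Log2 ratios were taken of CPM + 5, over the 7117 genes with at least 20 CPM in at least 1 of the 6 libraries, so that each contrast held the same genes, where the plan named only the libraries contrasted. There is 1 library per treatment, and no test of treatments was made; a model that adds the effects of the 3 RNAs across the 6 libraries was not fitted. Intervals are exact 95% Poisson, conditional ratio or Clopper-Pearson intervals and cover counting error only. Each single RNA was read in 2 contrasts that share no library, for example miR-124 mimic against control and triple against double combination. The let-7 and miR-25 pairs of contrasts were both formed from the control, let-7 antagomiR, miR-25 mimic and double combination libraries. A gene extreme in 1 of those libraries can thus be named for both RNAs. Genes are named by rules of size fixed before the data were examined: the 12 highest and 12 lowest by the smaller of the 2 log2 ratios for each RNA, the 8 highest and 8 lowest for each combination against control, the 2 highest and 2 lowest of each list, and 15 genes chosen whatever their values. One of the genes so named, with the results that need it, is not reported here. Mitochondrial, ribosomal protein, sex-linked, haemoglobin and unnamed (Gm, Rik) genes stayed out of the ranking. Medians of fixed gene lists were set against 10000 random lists of the same size matched on mean expression, as percentiles that describe these libraries.

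Sites pairing with bases of the miRNA seed were searched in annotated 3′ UTRs (GENCODE vM21, GRCm38) of 20592 genes. The planned measure was the median log2 ratio of genes with any 7-mer or 8-mer site. A scan over 7-mers was added after those medians had been seen: genes with and without each 7-mer were compared after removing quadratic trends of the log2 ratio on UTR length, mean expression and UTR GC, over 6991 genes and 14725 7-mers present in at least 100 genes, ranked by the difference divided by its standard error across genes, with counting intervals from 200 Poisson redraws. Tested on simulated data for the library labelled miR-124 against control, the scan ranked the simulated seed first in 6 of 6 simulations at a shift of 0.1 and recovered 76.8% to 88.5% of it. For both miR-124 contrasts, simulated counts of 7117 genes with 200 changed gave 90% of 50 genes raised 2.5-fold as at least 2-fold in both, 72% of 50 genes lowered to 0.4, and 0 of 6917 unchanged genes. Both simulations held counting error alone, with no other variation between libraries. They therefore give no rate of detection or of false calls for the real libraries.

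Marker-positive cells were counted after thinning each cell to 1500 UMIs and leaving out shallower cells; a cell counts when at least 3 genes of a list are detected. The alternatives tried were thinning to 1000 or 3000 UMIs, at least 2 genes per list, doublets kept, 20% mitochondrial UMIs, at least 1000 genes, all kept cells, a pseudocount of 1 CPM, median-of-ratios scaling, no level filter or 50 CPM, equal weight per cell, 8-mer sites only, resolutions 0.3 and 1.0, and values centred per library. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and leidenalg 0.10.2 was used.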

Results

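Müller glia, the main glial cells of the retina, were cultured from mice and transfected with RNAs that lower let-7 activity or add miR-25 or miR-124, singly and combined. There were 6 single-cell libraries, 1 for each treatment, so no difference given here has a replicate check. The matrices held 23124374 UMIs (unique RNA molecules counted) in the control, 21001735 with let-7 antagomiR, 21561243 with miR-25 mimic, 15059804 in the library labelled miR-124 mimic, 11804176 in the part of the double combination that was read, and 22705495 in the library labelled triple combination. After filtering, 4516, 3059, 5159, 3592, 2725 and 4078 cells remained in that order, with median depths of 4479, 5872, 3846, 3518.5, 3789 and 4576.5 UMIs. The word "labelled" is kept for the miR-124 and triple libraries because miRNA site genes in them go against part of their labels.

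Müller-like cells made up 29.4% of control cells (95% interval 28.0% to 30.7%), 50.3% with let-7 antagomiR, 57.8% with miR-25 mimic, 34.7% in the library labelled miR-124, 50.2% in the double combination and 55.3% in the library labelled triple combination. Fibroblast- or mesenchymal-like cells made up 48.1% of the control, where they were the largest class, and 29.2%, 21.6%, 34.4%, 28.1% and 22.2% of the other libraries in that order. Astrocyte-like cells made up 5.72% to 8.88% of each library, pericyte- or smooth-muscle-like cells 4.73% to 8.21%, and microglia- or macrophage-like cells 1.43% to 3.17%. Neuron- or progenitor-like cells made up 0.642% of the control (0.430% to 0.921%) and 3.82%, 4.42%, 5.96%, 3.34% and 1.99% of the other libraries in that order. At resolution 0.3 this class had 0.0221% of the control and 0.523%, 0.523%, 1.67%, 2.02% and 0.0736% of the others, so its size and the library with the highest share depend on the clustering. Culture and treatment cannot be separated in these shares, with 1 library each.

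Genes with miRNA sites in their 3′ UTRs served as the check on the labels. In the let-7 antagomiR library, genes with the let-7 site had log2 ratios to control higher by 0.073 than genes without it (counting interval 0.063 to 0.081), rank 1 from the highest of 14725 7-mers in Müller-like cells. In the miR-25 mimic library the miR-25 site gave -0.15, rank 1 from the lowest. The double combination had both, 0.084 for let-7 and -0.16 for miR-25, each again at rank 1. The miR-124 site was at rank 1 from the lowest in the libraries labelled miR-124 and triple combination, at -0.090 and -0.11. Ranks here are those of the difference divided by its standard error. The library labelled miR-124 also had let-7 site genes higher by 0.089 (0.077 to 0.099), rank 1 from the highest, although its label names no let-7 inhibitor. The library labelled triple combination had the let-7 site at 0.019 (0.010 to 0.028), rank 3099 from the highest, and the miR-25 site at 0.015 (0.0058 to 0.023), not below 0, although its label names both RNAs. Over the alternatives that last let-7 value ran from -0.015 to 0.024, that of the library labelled miR-124 from 0.034 to 0.10, and that of let-7 antagomiR from 0.024 to 0.081. The site of miR-9-5p, which no label names, stood at -0.045 and -0.046 in the libraries labelled miR-124 and triple combination. Site genes could thus also move for a miRNA that no label names, which limits this check. This scan of 7-mers was added after the planned medians had been seen.

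**Figure D1:**
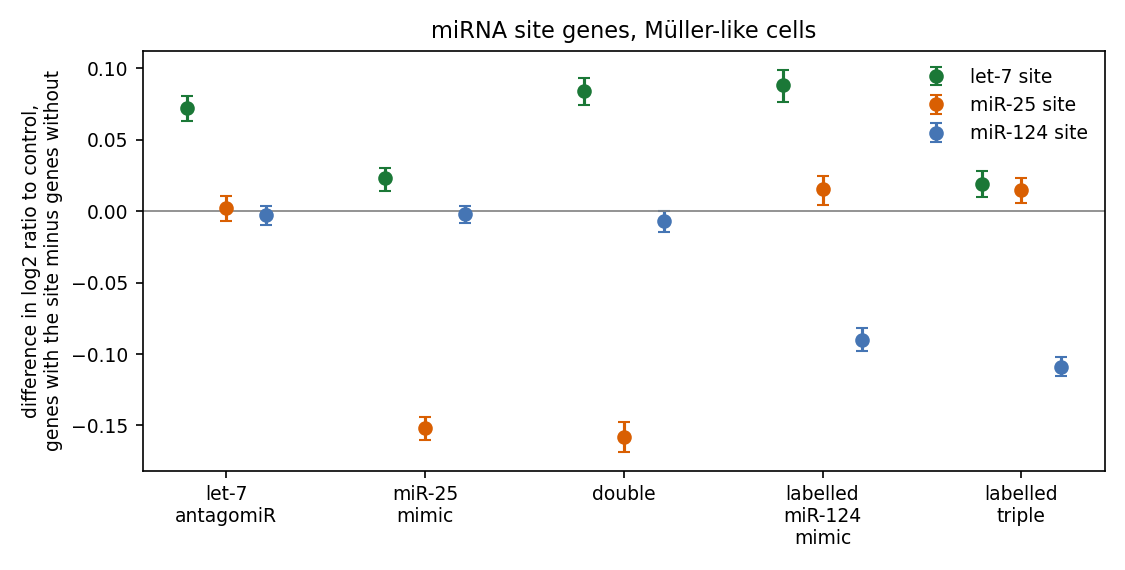
Points give, for each treated library, the difference in log2 ratio to control between genes with and without a let-7, miR-25 or miR-124 site in Müller-like cells, and bars give 95% counting intervals. The miR-25 site reaches -0.16 in the double combination and lies at 0.015 in the library labelled triple combination, while the let-7 site reaches 0.089 in the library labelled miR-124.

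The planned medians over all genes with a site were smaller. Their random lists were matched on expression alone, and lists of miRNAs that were not added could also leave the random range. With miR-25 mimic against control, miR-124 site genes fell below all random lists in fibroblast- and pericyte-like cells. They stood at percentile 0.27 in microglia-like and 12.5 in astrocyte-like cells. These percentiles alone thus do not show an effect of the RNA added. For miR-25 sites (1139 genes measured) the median log2 ratio was -0.071 for miR-25 mimic against control and -0.12 for the double combination against let-7 antagomiR, both below all matched random lists. Literature targets of miR-25 gave -0.19 and -0.30 over 25 genes. For let-7 sites (1214 genes) the medians were 0.023 and -0.011, at percentiles 99.97 and 100 of matched random lists, and literature targets of let-7 gave 0.23 and 0.27 over 17 genes, the first of which had the opposite sign over all kept cells. For miR-124 sites (1810 genes) they were 0.044 (percentile 13.6) and 0.10 (percentile 95.6), so this measure did not show lower miR-124 site genes in the libraries labelled with it. Median-of-ratios scaling turned the signs of these miR-124 medians and of the second let-7 median, but it moved the median of all genes the same way, so the turn says nothing about site genes. Literature targets of miR-124 gave -0.16 (percentile 0.28) and -0.22 (percentile 1.64) over 30 genes. Members went both ways, as Itgb1 was lower and Sox9 higher in both contrasts.

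The contrasts labelled miR-124 ask what this neuronal miRNA does to Müller glia. Gfap, an intermediate filament of reactive glia, stood at 464 CPM (counting interval 442 to 487) in the library labelled miR-124 against 45.1 (39.6 to 51.1) in the control, and at 1086 CPM in the library labelled triple combination against 30.9 in the double combination. Glul, which encodes glutamine synthetase, and Rlbp1, a retinoid carrier of Müller glia, were higher by 1.63 and 2.14 (log2) in the first contrast and by 2.61 and 3.33 in the second. Igfbp2, a growth factor binding protein, was lower, at 347 CPM against 1344 and at 324 CPM against 1497.

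Nptx1, Pcdh15, Car14, Aldoc, Id2, Tmem132b, Mmd2, Tox2, Cacng4 and Nav1 were also among the genes named as highest in both contrasts, and Gpnmb, Nupr1, Sfrp1, Tinagl1, Grem1, Ctsd, Col8a1, Gja1, Ccnd2, Akr1c18 and Igfbp3 as lowest. Col8a1 had the opposite sign over all kept cells. Car14, Nptx1, Pcdh15 and Cacng4, like Glul and Rlbp1, are among the leading genes of the Car14-led cluster. That cluster held most Müller-like cells of the libraries labelled miR-124 and triple combination. Grem1 and Akr1c18 are among the leading genes of the Grem1-led cluster. Sox9, a glial transcription factor that is on the list of miR-124 literature targets, was higher by 0.61 and 0.85, and Hes1, a Notch effector, by 1.02 and 0.35. The neuron list (7 genes measured) had medians of 0.41 and 0.45, at percentiles 97.4 and 85.2 of matched random lists, but the first was -0.31 with at least 50 CPM. Of its members, Tubb3 had log2 ratios of -0.21 and 0.21, Stmn2 of -0.87 and -1.23, and Dcx had 3 or fewer UMIs in the Müller-like cells of every library. Rest, a repressor of neuronal genes, stood between 69.6 and 97.3 CPM in the 6 libraries. Ptbp1, a splicing repressor targeted by miR-124, had log2 ratios of -0.39 and 0.41.

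The medians of the next 9 gene groups lay outside the 95% range of matched random lists in both contrasts. Of 20 Müller glia genes, 12 were at least 1.5 times higher and 1 lower in the first contrast, and 15 and 1 in the second, with medians of 0.78 and 1.18. This list also served to name the Müller-like clusters, and 16 of its genes were at least 2-fold over the median cluster in the Car14-led cluster. Of 8 measured neurogenic progenitor genes, 7 and 8 were higher (medians 1.75 and 1.505), and of 8 Notch pathway genes, 5 in each (0.97 and 1.41), among them Hes6 at 134 CPM against 35.5. The progenitor and Notch lists share Hes5, Hes6, Dll1, Dll3 and Mfng, so they are not separate results. Of 20 actin and adhesion genes, 12 and 13 were lower and 0 higher, with medians of -0.94 and -1.20, led by Itgb1 and Tpm2. The pericyte or smooth muscle list (4 genes measured), markers of a contractile cell type, moved the same way, with medians of -0.79 and -1.71. Of 17 matrix and collagen genes, 11 and 15 were lower, with medians of -0.71 and -0.82, but the second median had the opposite sign over all kept cells. Medians were also below 0 for p53 targets (-0.47 and -0.95) and interferon genes (-0.47 and -0.51). Immediate early genes, which respond to stimulation and to dissociation, had medians of 0.74 and 0.88, with Fos at 1827 CPM against 859. These medians were nearer to 0 over all kept cells: 0.53 and 0.83 for Müller glia, 0.44 and 0.95 for progenitor, 0.28 and 0.20 for Notch, -0.053 and -0.18 for actin and adhesion, -0.11 and -0.11 for pericyte, -0.13 and -0.52 for p53, -0.085 and -0.082 for interferon and 0.26 and 0.49 for immediate early genes. Without a level filter the progenitor medians were 0.53 and 0.18 and the Notch medians 0.031 and 0.35. The reactive gliosis list, to which Gfap belongs, had medians of -0.49 and -0.12, with 3 of 18 genes at least 1.5 times higher and 6 lower in the first contrast, and 6 and 4 in the second.

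Among 7117 genes, 166 were at least 2-fold higher in both contrasts and 74 lower, against 14.9 and 5.55 for independent lists, but over all kept cells these counts were 76 and 6. The 2 contrasts share no library, and across genes, which are not independent replicates, their log2 ratios correlated at r = 0.656. Most Müller-like cells of the libraries labelled miR-124 (691 of 1246) and triple combination (1727 of 2256) lay in the cluster led by Car14, and most of the other libraries in those led by Grem1 and Lcn2, so these values also compare those clusters. The first contrast also carries the higher let-7 site genes of the library labelled miR-124, and the second the missing let-7 and miR-25 differences. Neither can be read as miR-124 alone.

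**Figure D2:**
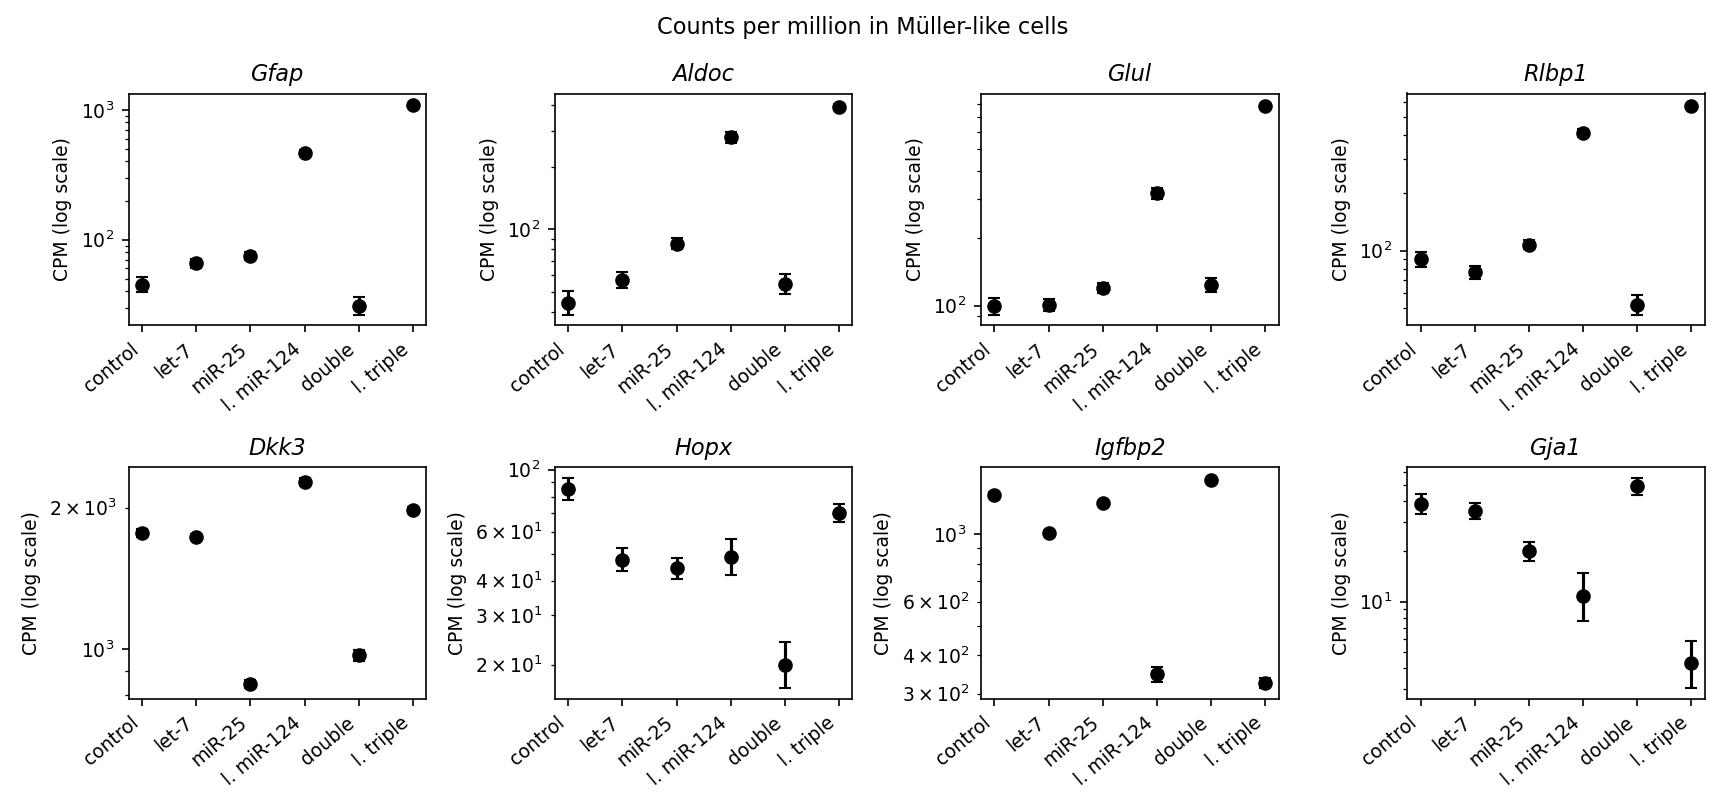
Each panel plots 1 gene's CPM in Müller-like cells on a log scale for the 6 libraries (l. marks the libraries labelled miR-124 and triple combination), with bars for 95% Poisson intervals. Gfap, Aldoc, Glul and Rlbp1 are highest in those 2 libraries, with Gfap at 1086 CPM, and Dkk3 is lowest with miR-25 mimic, at 843 CPM.

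The let-7 contrasts ask what loss of let-7 activity does. AI593442 stood at 67.7 CPM (62.5 to 73.3) with let-7 antagomiR against 19.0 (15.5 to 23.1) in the control, and at 135 CPM in the double combination against 12.7 with miR-25 mimic. Npvf, a neuropeptide precursor, stood at 720 CPM against 315 and at 560 CPM against 215. A2m, a protease inhibitor, was lower, at 504 CPM against 1008 and at 239 CPM against 581. Of 18 reactive gliosis genes, 5 and 6 were at least 1.5 times lower and 0 higher, with medians of -0.29 and -0.36, Lcn2 standing at 470 CPM against 716 and at 428 CPM against 1326. The second contrast also compares clusters. The Grem1-led cluster, whose leading genes include AI593442, Npvf and R3hdml, held 1169 of 1369 Müller-like cells of the double combination against 1665 of 2982 with miR-25 mimic. The Lcn2-led cluster held 196 against 1301.

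R3hdml, Htra3, Spp1, Col4a2, Plppr1, Slc16a12, Pacsin1, Tsc22d1, Col4a3 and Mest were the other genes named as highest in both let-7 contrasts, and Crygs, Sept4, Hopx, Hkdc1, Krtap16-3, Serpina3n, Mbd1, Nfasc, Slc6a11, Ccnd1 and Qrfpr as lowest. Spp1, Col4a2, Nfasc and Slc6a11 had the opposite sign against control over all kept cells. Hmga2, a well-known let-7 target, had log2 ratios of -0.016 and 1.15, Igf2bp1 of 0.14 and -0.31, and Lin28b had 0 UMIs in the Müller-like cells of all libraries but the double combination, which had 1. Of 7117 genes, 5 were at least 2-fold higher in both contrasts and 0 lower, against 0.0475 and 0.0124 for independent lists, and r across genes was 0.267. The higher count was 3 over all kept cells and 8 with a pseudocount of 1 CPM, which also gave 1 lower gene.

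The miR-25 contrasts ask what added miR-25 does. Dkk3, a secreted Wnt pathway regulator and known miR-25 target, stood at 843 CPM (826 to 860) against 1765 (1730 to 1801) in the control, and at 970 CPM in the double combination against 1731 with let-7 antagomiR; the library labelled triple combination had 1972. Ccl2, a chemokine, was higher, at 81.6 CPM against 27.9 and at 108 CPM against 31.2. Of 14 interferon genes, 5 and 4 were at least 1.5 times higher and 0 lower, with medians of 0.41 and 0.29, among them Isg15 and Bst2, the latter at 190 CPM against 106.

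Hopx, Insig1, A2m, Chl1, Peak1, Nptn, Ergic2, Crym, Mia3, Cntn1 and Zdhhc5 were the other genes named as lowest in both miR-25 contrasts, and R3hdml, Ptn, Foxj1, Pacsin1, Wisp2, Akr1c18, Qrfpr, Nme5, Htra3, Ptgds and Isg15 as highest. A2m, Chl1, Crym and Cntn1 had the opposite sign against control over all kept cells. R3hdml, Htra3 and Pacsin1 were also named as highest, and A2m and Hopx as lowest, in the let-7 contrasts, where Qrfpr was among the lowest. The let-7 contrasts are formed from the same libraries, so these genes are not separate results for each RNA. Cluster mix enters the second contrast here too. The Grem1-led cluster, whose leading genes include R3hdml and Akr1c18, held 1169 of 1369 Müller-like cells of the double combination against 1030 of 1539 with let-7 antagomiR. The Lcn2-led cluster held 196 against 505. Of 7117 genes, 8 were at least 2-fold higher in both contrasts and 0 lower, against 0.0974 and 0.0298 for independent lists, and r across genes was 0.351. With a pseudocount of 1 CPM these counts were 14 and 1, and 2 genes were lower over all kept cells.

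The combinations ask how the RNAs act together. In the double combination Acta1, a muscle actin, stood at 101 CPM (93.2 to 110) against 7.95 in the control, and Crym, a thyroid hormone binding protein, at 559 CPM against 1939. Acta1, R3hdml, AI593442, Htra3, Pacsin1, Ptn, Akr1c18 and Kcne1l were highest, and A2m, Hopx, Crym, Adam23, Mt3, Scn7a, Mme and Chl1 lowest. R3hdml, AI593442 and Akr1c18 are among the leading genes of the Grem1-led cluster. That cluster held 1169 of 1369 Müller-like cells of the double combination against 847 of 1326 in the control, and the Lcn2-led cluster 196 against 472. These values thus also compare clusters. The Müller glia and progenitor lists had medians of -0.40 and -0.38, of which the first had the opposite sign over all kept cells and the second without a level filter. In the library labelled triple combination Gfap, Car14, Nptx1, Pcdh15, Cacng4, Ndrg2 and Aldoc were among the highest, and Tinagl1, Grem1, Alcam, Gja1, Col8a1, Tmem37, Igfbp2 and Ccnd1 lowest, and its Müller glia and progenitor lists had medians of 0.62 and 1.07. Car14, Nptx1, Pcdh15 and Cacng4 are among the leading genes of the Car14-led cluster. It held 1727 Müller-like cells of that library against 7 in the control, so clusters are compared here too.

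Against control, 47 genes were at least 2-fold higher and 54 lower in the double combination, and 295 and 213 in the library labelled triple combination. Alternatives gave 82 higher and 112 lower at most in the double combination, and 194 higher and 40 lower at least in the library labelled triple combination. Log2 ratios of the combinations correlated across genes with the sum of the single ones at r = 0.613 for the double combination and 0.684 for the library labelled triple combination, with slopes of 0.579 and 0.560. These contrasts all share the control library, and unchanged libraries simulated with the same depths gave r of 0.634 and 0.700 and slopes of 0.395 and 0.260 for the same comparison, so r does not show that effects add. Covariances were 0.0830 and 0.252, against 0.0144 and 0.0216 in the simulation, which has counting error alone. Single contrasts against that control had r of 0.222 to 0.381 and covariances of 0.0195 to 0.0268 with each other, where unchanged libraries simulated against it gave r of 0.499 to 0.654 and covariances of 0.00717 to 0.00718.

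Neuron-marker cells, those with at least 3 genes of the neuron list, made up 0.792% of control cells (interval 0.552% to 1.10%) after thinning to 1500 UMIs. Their share was 1.41% with let-7 antagomiR, 1.64% with miR-25 mimic, 3.16% (2.61% to 3.79%) in the library labelled miR-124, 1.97% in the double combination and 1.72% in the library labelled triple combination. Müller-like cells had 1.56% in both the control and the library labelled miR-124, at median depths of 3973 and 2671.5 UMIs. In the neuron- or progenitor-like class, 5 of 29 control cells and 81 of 199 cells of the library labelled miR-124 were neuron-marker cells. Fibroblast-like cells had 0.375% and 0.245%, at median depths of 4623 and 4380.5 UMIs. The list is not specific to neurons here, as Stmn2 was detected in 21.0% and 25.1% of fibroblast-like cells. It was also in 91.4% of neuron-marker cells of the control and 56.8% of those of the library labelled miR-124, where Dcx was in 0% and 7.21%. Unthinned, the shares ran from 5.89% in the control to 12.5% in the library labelled triple combination, and 6.18% to 8.43% of thinned cells had exactly 2 genes. Cells too shallow for thinning numbered 98, 0, 162, 81, 130 and 0 in the order given above. The ratio to control of the library labelled miR-124 was 3.99 (2.71 to 6.01), but 8.49 after thinning to 1000 UMIs and 1.48 when 2 genes were enough.

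Neurogenic-progenitor-marker cells made up 2.87% of control cells, 5.59% with let-7 antagomiR, 7.26% with miR-25 mimic, 11.7% in the library labelled miR-124, 3.31% in the double combination and 16.7% in the library labelled triple combination. Ratios to control were 1.94, 2.53, 4.06, 1.15 (0.866 to 1.53) and 5.83, and that of let-7 antagomiR was 0.98 when 2 genes were enough. These are ratios over all kept cells, so the mix of cells enters. Müller-like cells made up 29.4% of the control, 50.3% with let-7 antagomiR, 57.8% with miR-25 mimic and 50.2% of the double combination. Ratios among neural classes alone were not taken for progenitor-marker cells. Unthinned, the shares ran from 13.8% in the double combination to 48.0% in the library labelled triple combination, and fibroblast-like cells had 1.64% to 2.21%. Mki67, a proliferation marker, stood at 1.39 to 3.51 CPM in Müller-like cells. Cycling-marker cells made up 0.540% to 0.771% of each library, and every ratio to control had an interval that included 1.

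**Figure D3:**
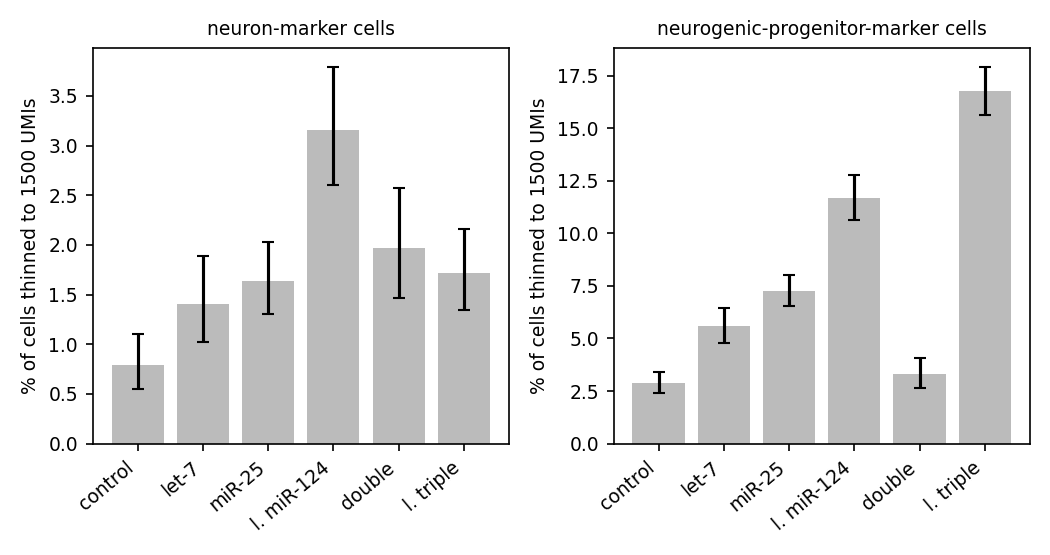
Bars give the percent of cells, thinned to 1500 UMIs, that carry neuron markers or progenitor markers in each of the 6 libraries (l. marks the libraries labelled miR-124 and triple combination), with 95% Clopper-Pearson intervals. The neuron-marker share is highest in the library labelled miR-124, at 3.16%, and the progenitor-marker share in the library labelled triple combination, at 16.7%.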

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

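All tests of explanations here were chosen after the result was seen, except that of immediate early genes in fibroblast-like cells.

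The let-7 site in Müller-like cells had opposite signs in the comparisons that, by their labels, add let-7 antagomiR and miR-25 mimic. It stood at 0.084 in the double combination against control. In the library labelled triple combination against that labelled miR-124 it stood at -0.070. The second value follows from the higher let-7 site of the library labelled miR-124 and is not a separate result. The let-7 site of the library labelled triple combination was itself higher against control. The difference was not tested.

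The let-7 and miR-25 site genes of the libraries labelled miR-124 and triple combination go against their labels, and a single wrong label cannot give both departures, since the let-7 site stood at 0.089 (counting interval 0.077 to 0.099) in the first and the miR-25 site at 0.015 in the second. An exchange of these 2 labels would need lower miR-25 site genes in the library labelled miR-124, where the site stood at 0.015 (counting interval 0.0045 to 0.024) against -0.16 in the double combination. A state shared by the Car14-led cluster would raise let-7 site genes in that cluster of both libraries, but it had 0.12 in the library labelled miR-124 and 0.016 in that labelled triple combination. Competition of the added RNA with other miRNAs in general would raise their site genes too, where the median over 16 other families was 0.00049 in the library labelled miR-124. The values ran from -0.045, for miR-9-5p, to 0.018. The activity of those families in these cells was not measured, so this median cannot exclude competition that acts mainly on let-7. With miR-25 mimic, whose label names no let-7 inhibitor, the let-7 site stood at 0.023 outside the Car14-led cluster. Weaker uptake of every RNA given together would weaken the miR-124 site in the library labelled triple combination, where it stood at -0.11 against -0.090. These values cannot decide, since the 2 libraries differ in the share of cells in the Car14-led cluster. The site stood at -0.15 in that cluster of both libraries, and at -0.010 against -0.022 in their other Müller-like cells. Outside that cluster the double combination was not weaker than the single RNAs. Its let-7 site stood at 0.084 against 0.073 and its miR-25 site at -0.16 against -0.15. Wrong labels of both libraries other than an exchange, competition that acts mainly on let-7, and an interplay of the RNAs in the cells stay open and were not tested. Weaker uptake in the library labelled triple combination stays open too.

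Neuron-marker cells stood above the control in every treated library. A smaller share of fibroblast-like cells does not account for the library labelled miR-124, where the ratio to control among Müller-, astrocyte- and neuron- or progenitor-like cells alone was 3.81 (2.44 to 6.16), nor does free RNA, since 0.245% of its fibroblast-like cells carried these markers. In the double combination, at 1.96 (1.19 to 3.31), the library labelled triple combination, at 1.61 (1.003 to 2.66), and with let-7 antagomiR and miR-25 mimic, at 1.42 (0.842 to 2.43) and 1.44 (0.904 to 2.35), a change in the mix of cells and a change in neuron-marker cells cannot be told apart, since these intervals cover counting error of 1 library each and reach near or below 1. Doublets cannot be told apart in the library labelled miR-124, as the ratio of 3.97 without the highest doublet scores rests on a caller that did not work there, and that of 4.06 (2.73 to 6.20) without the unnamed mixed cluster does not show where its other doublets lie. Neurons surviving from the dissociated retina, and a response to the RNAs, were not tested and stay open.

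The progenitor list was higher together with the immediate early list, with which it shares Btg2, in both contrasts labelled miR-124. Handling or dissociation that reached all cells would raise immediate early genes in fibroblast-like cells too, where the lower of the 2 medians was -0.076. Handling that acts on glia alone stays open, as immediate early genes in astrocyte-like cells had medians of 0.71 and 0.41, and so does a response of glia to miR-124, which was not tested. The class did not hold the same cells in every library, as 691 of 1246 and 1727 of 2256 lay in the Car14-led cluster in those labelled miR-124 and triple combination, and whether cells changed their state or other cells were sampled stays open.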

How the results depend on the processing

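The added alternatives, leaving out the highest doublet scores or the unnamed cluster and the scan of 7-mers, were chosen after seeing the data. No paired analysis was made because each treatment has 1 library, and the comparisons come from no test. Of alternative values, 1517 gene list medians, 162 site medians, 102 marker-cell ratios, 98 site 7-mer values, 77 gene counts and 17 class shares stayed within their limits; 118 (76 nearer to 0), 62, 17, 37 (19 nearer to 0), 13 and 19 (12 nearer to 0) moved, and 13 list medians, 16 site medians and 1 marker-cell ratio that had lain outside their random range or interval changed sign or side of 1. Counting medians inside the random range too, 91 list medians and 23 site medians changed sign. Median-of-ratios scaling took the median of all genes in triple against double combination from 0.073 to -0.046, and site medians are to be read relative to it. The cause was not tested where none is given. Depth limits the library labelled miR-124 most, where 3 UMIs in Müller-like cells make 0.835 CPM, against 0.257 with miR-25 mimic. In the following, triple and miR-124 stand for the libraries so labelled.

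Over all kept cells, where cell mix enters, genes at least 2-fold higher and lower in both miR-124 contrasts numbered 76 and 6, higher in both let-7 contrasts 3, lower in both miR-25 contrasts 2, higher in the double combination 82 and lower in the triple combination 40. With a pseudocount of 1 CPM, which widens ratios of low genes, the let-7 counts were 8 higher and 1 lower, the miR-25 counts 14 higher and 1 lower, and those of the double combination 71 higher and 112 lower. With at least 50 CPM, which tests fewer genes, 194 were higher in the triple combination.

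Over all kept cells these medians, outside the random range before, changed sign: Müller glia 0.24 (double combination against control), neuron 0.30 and let-7 literature targets -0.0078 (let-7 antagomiR against control), interferon 0.0097 (triple against control), reactive gliosis 0.025, unfolded protein -0.048 and matrix and collagen -0.0096 (double combination against let-7 antagomiR), cholesterol 0.14 (miR-124 against control) and matrix and collagen 0.051 (triple against double combination). Without a level filter the progenitor list of the double combination against control had 0.033. With at least 50 CPM the neuron list had -0.29 in the triple combination against control, and the REST list -0.18 in the double and -0.65 in the triple combination against control.

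Let-7 site medians for let-7 antagomiR against control were 0.046 over all kept cells and 0.0039 without a level filter. Against control with miR-25 mimic they were -0.040 with median-of-ratios scaling, -0.0017 with at least 50 CPM, -0.0072 with 20% mitochondrial UMIs and -0.0006 with equal weight per cell. With median-of-ratios scaling they were 0.050 for the double combination against miR-25 mimic and -0.0002 for triple against control. MiR-25 site medians for let-7 antagomiR against control were 0.024 over all kept cells and 0.0043 with at least 50 CPM. For miR-25 mimic against control they were -0.014 over all kept cells, -0.12 with median-of-ratios scaling, -0.023 without a level filter and -0.22 with 8-mer sites. For the double combination against let-7 antagomiR they were -0.093 over all kept cells, -0.043 without a level filter, -0.15 with at least 50 CPM and -0.29 with 8-mer sites.

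MiR-124 site medians for miR-124 against control were 0.020 over all kept cells, -0.012 with median-of-ratios scaling, 0.0025 without a level filter and -0.023 with 8-mer sites. For triple against double combination they were 0.063, -0.016, 0.039 and 0.071 in that order, and 0.041 with at least 50 CPM. For triple against control they were -0.055 with median-of-ratios scaling, -0.021 with at least 50 CPM and -0.018 with 8-mer sites, and for let-7 antagomiR against control 0.030 over all kept cells. For miR-25 mimic against control they were -0.043 with median-of-ratios scaling, -0.0096 with 20% mitochondrial UMIs, -0.0057 with equal weight per cell and -0.0076 with 8-mer sites.

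Neuron-marker ratios to control, in the order let-7 antagomiR, miR-25 mimic, miR-124, double and triple combination, were 1.03, 1.37, 1.48, 1.27 and 1.31 when 2 genes were enough. Thinning to 1000 UMIs gave 2.95, 4.46, 8.49 and 5.25 in the first 4, and thinning to 3000 gave 1.97 for miR-124 and 1.496 for the double combination. Progenitor-marker ratios when 2 genes were enough were 0.98 for let-7 antagomiR, 1.25 for miR-25 mimic, 1.52 for miR-124 and 1.72 for the triple combination. Thinning to 3000 UMIs gave 1.89 for miR-25 mimic, 2.42 for miR-124 and 3.99 for the triple combination.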

Other observations

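The scan of 7-mers, on which the first 2 paragraphs rest except where medians are named, was chosen after the planned medians had been seen. The list values after those paragraphs were planned.

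Site differences were also taken in other cell classes, which differ in size and depth, and no difference between classes was tested. In astrocyte-like cells the miR-25 site stood at -0.12 with miR-25 mimic and -0.14 in the double combination, the let-7 site at 0.056 and 0.068 with let-7 antagomiR and in the double combination, and the miR-124 site at -0.087 and -0.095 in the libraries labelled miR-124 and triple combination. As in Müller-like cells, the let-7 site was above 0 in the library labelled miR-124, at 0.050, and the miR-25 site was not below 0 in that labelled triple combination, at 0.0038. Microglia- or macrophage-like cells, 71 to 123 per library, had the miR-25 site at -0.057 with miR-25 mimic, rank 117 from the lowest, and at -0.14 in the double combination, rank 1, while the miR-124 site stood at -0.00097 and 0.0041 in the libraries labelled miR-124 and triple combination. Fibroblast-like cells had -0.019 and -0.038 at the miR-25 site with miR-25 mimic and in the double combination.

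Within Müller-like cells the miR-124 site stood at -0.15 in the Car14-led cluster of both libraries labelled with miR-124, and at -0.022 and -0.010 in their other Müller-like cells. The let-7 site outside the cluster stood at 0.050 in the library labelled miR-124, rank 1 from the highest, and at 0.026 in that labelled triple combination, rank 213.

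Cholesterol synthesis genes of Müller-like cells had a median of 0.25 with miR-25 mimic against control but -0.25 in the double combination (-0.020 over all kept cells), where Insig1, a brake on this pathway, stood at 60.7 CPM against 161. Inflammatory cytokine genes had medians of -0.46 and -0.89 in the contrasts labelled miR-124, and the unfolded protein list -0.12 and -0.48. Genes of miRNA processing had 0.23 and 0.25, glycolysis and hypoxia genes 0.077 and 0.26, neuronal splicing genes 0.21 and 0.26, and BMP and TGF-beta genes -0.073 and -0.37. The REST list (5 genes) had -0.21 and 0.21, and the astrocyte list (8 genes) 0.15 and 0.78. Some of these signs turned: over all kept cells the first median was 0.11 for the unfolded protein list, 0.195 for BMP and TGF-beta genes and 0.49 for the REST list, and with at least 50 CPM the second was 0.072 for BMP and TGF-beta genes and -1.20 for the REST list. The first also turned for BMP and TGF-beta genes with at least 50 CPM (0.025), and for the REST list with 20% mitochondrial UMIs (0.29) and without a level filter (0.10).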
